A study of Caenorhabditis elegans with 12 samples.

How the data were processed

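RNA was sequenced from 12 pools of whole wild-type (N2) Caenorhabditis elegans, 6 treated with vitamin D and 6 treated with the vehicle, dimethyl sulfoxide (DMSO). Per the labels' protocols, libraries had an average insert of 200 bp and were read as pairs of 50 bp on a HiSeq 2000. Library strand, aligner, counting tool, genome build and annotation are not given in the sources used here. The only tool named in the submitters' processing notes is edgeR 3.12.1.

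The authors deposited a table of raw read counts per gene, with 27928 genes in rows and the 12 libraries in columns, and a table of CPM (counts scaled to a library total of 1e+06). Every deposited CPM value equalled the count divided by its library's total to within 2.91e-11, so the CPM table holds no further normalization and was used only for that check. Columns were matched to samples by the sample descriptions in the labels, and only these 12 columns were used. Gene identifiers were matched by sequence name to the Ensembl annotation of the WBcel235 assembly: 27187 matched a single gene, 3 matched several and 738 matched none. The unmatched identifiers held 0.518% to 0.653% of the counts of a library and stayed in the tests under their own names. Coordinates and exon lengths are those of WBcel235, since the build behind the deposited counts is not given in the sources used here.

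Total counts ran from 30203731 to 35230983 in the vehicle libraries and from 31383203 to 38720736 in the vitamin D libraries. At this depth 13460 genes passed edgeR's filterByExpr, with a minimum count of 10 and a minimum total of 15, and these genes held 99.928% to 99.967% of the counts. No 2 libraries of a group were alike within sampling noise: the lowest chi-square per degree of freedom between libraries of a group was 7.8 (vehicle libraries 5 and 6). No library's counts are thus a copy of another's. The value was 9.4 for vehicle libraries 2 and 3 and 8.8 to 14.5 among vitamin D libraries 2, 3 and 4. Other pairs of a group reached 356.8. Whether the close pairs share a source population or RNA cannot be read from these values. That each is an independent replicate rests on the series text.

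Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. The fit used TMM factors, a design with the treatment as its only term, and robust quasi-likelihood dispersions (glmQLFit and glmQLFTest). Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 13460 tested genes passed the threshold. Log2 fold changes are vitamin D over vehicle, with standard errors derived from the fit, and CPM values in the text are scaled by the TMM factors. The common biological coefficient of variation was 0.313. All tests were two-sided unless stated. The p-values of edgeR and of the permutations of libraries measure the spread between pools, which the series text calls independent biological replicates. Camera with the preset correlation rests mainly on a comparison between genes, and the neighbour tests permute genes. The p-values of both do not measure the spread between pools.

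Lists of genes were tested with camera in limma 3.58.1 on voom values with a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. In both fits with the length correction described below, camera used unweighted log2 counts less the offsets, with a trend in variance. Its p-values there differ from the main ones through this change of input as well as through the length trend. The lists covered SKN-1 phase II detoxification, the ER unfolded protein response with ER-associated degradation (ERAD), abu/pqn paralogs, the cytosolic heat shock response, the mitochondrial unfolded protein response and the proteasome. They also covered DAF-16 targets, antioxidant enzymes, xenobiotic cytochromes P450 and UGTs, nuclear receptors related to the vitamin D receptor (VDR) with steroid enzymes, vitellogenins, collagens and cuticle genes, the molting cycle, innate immunity, lipid metabolism, oxidative phosphorylation, and autophagy and the lysosome. Cell type and stage lists were sperm, oocyte and germline, embryo, intestine, neuron, body wall muscle, pharynx and hypodermis. Classes defined by symbol were cytosolic ribosomal proteins, histones, major sperm proteins, collagens and C-type lectins. A list of the protein-coding genes of the mitochondrial genome had no member with a count, and the 24 entries of that genome in the table held 0 counts. Separately, all 110 classes of genes with the same symbol prefix and at least 10 tested members were tested with camera, adjusted over the classes.

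The lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named the 10 genes with the highest and the 10 with the lowest log2 fold change among genes past the threshold with a mean of at least 1 CPM, the 5 smallest p-values per direction, 18 genes of the pathways in the title and their readouts, and up to 4 genes with the smallest p in each list and in each class past the threshold. Genes named beyond this rule are said to have been chosen after their values were seen.

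The alternatives fixed beforehand were DESeq2's size factors, no TMM, upper quartile factors, other count filters, DESeq2 1.42.0, limma voom with and without sample quality weights, limma trend, edgeR's exact test, a minimum 1.5-fold change (glmTreat), a stricter threshold of 0.01, the replicate number as a block, the first surrogate variable of sva 3.50.0, and leaving out each library in turn. Alternatives added after seeing the data were a correction for exon length (a spline with 5 degrees of freedom per library, removed through offsets), a stage score as a covariate (the first principal component of the sperm, vitellogenin, abu/pqn and molting lists), both together, and a fit without vehicle libraries 2 and 3 and vitamin D libraries 1 and 5. That fit leaves stage scores of 0.84 to 1.41 in vehicle and -0.41 to -0.07 in vitamin D libraries, so stage and treatment coincide in it. The stage score is built from lists that are also tested, so fits with it cannot test those lists independently. Library properties were compared with exact permutation tests over all splits of the 12 libraries, adjusted over 10 properties. The reference held no genome sequence, so GC content was not analysed here. Reads shared between paralogs, overlapping genes or antisense partners cannot be told apart in these counts. Some such genes are named as uncertain below, but members of other gene families reported without that remark may be affected too.

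The edgeR step was tested on simulated counts for 13314 genes with the means and library sizes of this comparison. Each gene was drawn independently, and changes were planted only in genes above 5 CPM. The step called 25 of 67 genes changed 1.5-fold (37.3%), 50 of 67 changed 2-fold (74.6%) and 63 of 66 changed 4-fold (95.5%). Of its 143 calls 5 were unchanged genes. Variation shared between genes, such as the first principal component of these libraries, was not simulated. The share of false calls in the real data may therefore be higher. The length correction was tested on 13342 simulated genes with a planted length trend, linear in log exon length and equal in all vehicle libraries. It lowered false calls from 2837 to 36 and kept 36 of the 40 true changes, against 37 before. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.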

Results

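The 12 RNA-seq libraries came from pools of whole wild-type (N2) worms kept for 44 h at 20 °C on vitamin D or on the vehicle, 6 pools per treatment. The labels disagree on 3 points: the dose (100 µM in the series text, 100 mM in the protocol), the worms per pool (50 or 40) and the start of treatment (the L4 larval stage, or 1 day of age). Vehicle libraries held 32550464 ± 2124854 counts (SD, n = 6) and vitamin D libraries 36265448 ± 2635573 (SD, n = 6), an exact permutation p of 0.0281 (0.0469 adjusted over 10 library properties). The series title places the study on protein homeostasis and longevity and names SKN-1, a transcription factor that drives detoxification genes, and IRE-1 and XBP-1, the sensor and the transcription factor of an arm of the unfolded protein response of the endoplasmic reticulum (ER). The question for these data was therefore which transcripts, those of the named pathways included, differed between worms on vitamin D and worms on vehicle.

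All 2800 table entries on chromosome III of the WBcel235 annotation held 0 counts in all 12 libraries, as did the 24 entries of the mitochondrial genome, 0 of which are protein-coding. The gene xbp-1 (R74.3) lies on that chromosome, was listed at 0 and gave no measurement. The same held for other list members, such as 7 of 32 proteasome genes, and every count over a list below is over its tested members.

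Libraries of the same treatment differed widely, and the axis of that difference carried germline, abu/pqn and molting genes. The first principal component of the 1000 most variable genes held 64.9% of the variance, and its values ran from -52.3 to 51.6 among vehicle libraries and from -41.9 to 21.2 among vitamin D libraries. No difference between the group means on it was detected (difference -20.4, exact permutation p = 0.325, n = 6 and 6). That test compares means only, and the groups were placed differently. Vehicle libraries 2 and 3 lay at -42.4 and -52.3, and the other vehicle libraries at 28.2 to 51.6, above all vitamin D libraries. The median log2 deviation of the 61 tested sperm genes was -1.53 and -1.78 in vehicle libraries 2 and 3 and lay between 0.85 and 1.33 in the other vehicle libraries, with -0.48 to 0.63 in the vitamin D libraries. The molting median went the other way, with 0.59 and 0.38 in vehicle libraries 2 and 3 and -0.52 in vehicle library 4. Yet 13 of the 38 molting genes rose with the sperm genes along a first component built without the stage lists. The abu/pqn median also went with the sperm genes, at -2.05 and -2.80 in vehicle libraries 2 and 3. It was 1.48 to 1.90 in the other vehicle libraries.

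**Figure D1:**
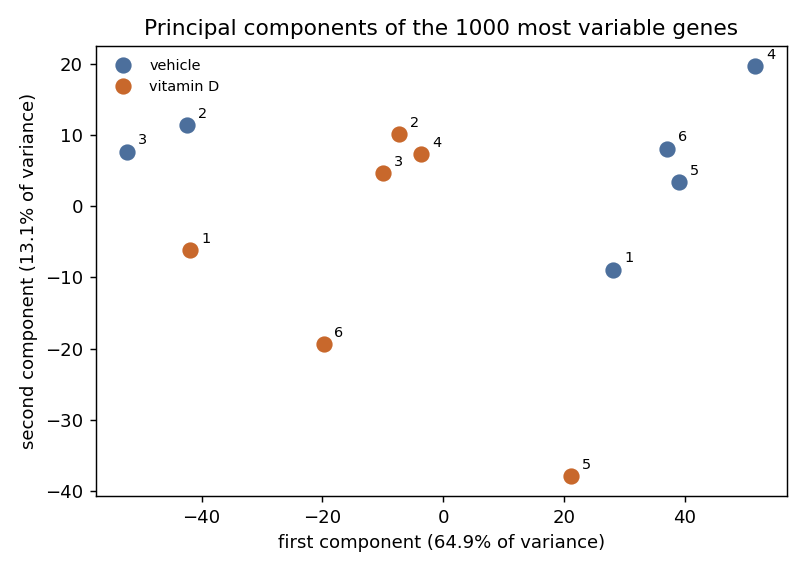
Values of the 12 libraries on the first principal component (horizontal, 64.9% of the variance) and the second (vertical, 13.1%) of the 1000 most variable genes, in component units, coloured by treatment and numbered by replicate. Vehicle libraries 2 and 3 lie at the left end, and the other vehicle libraries lie at the right end.

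Worms on vitamin D carried far more transcript of single enzyme genes such as R05D8.7, dhs-23, stdh-2 and nta-1. The gene with the highest fold change, R05D8.7, a predicted short-chain dehydrogenase, rose from 0.499 ± 0.239 to 13.8 ± 3.08 CPM (SD, n = 6 and 6), 27.5-fold. The most certain change was in cdr-4, a gene named for its response to cadmium, which rose 9.40-fold from 43.7 ± 2.28 to 411 ± 48.4 CPM (edgeR adjusted p = 3.62e-10). The ribosomal protein genes rpl-29 and rpl-38 fell from 821 ± 314 to 357 ± 25.4 CPM and from 1030 ± 301 to 538 ± 16.8 CPM. Transcripts of skn-1 and ire-1 did not pass the threshold.

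In all, 492 of 13460 tested genes passed the threshold in edgeR's quasi-likelihood test, 236 higher and 256 lower with vitamin D, and 2247 had an unadjusted p under 0.05. At least a 2-fold change was found for 99 of the higher and 41 of the lower genes. The values of the 6 vitamin D libraries lay wholly above or below those of the 6 vehicle libraries for 395 of the 492 genes. These genes were called from the same values, so little overlap among them is built in. Among all tested genes the share was 3.9%, against 0.216% by chance. Genes vary together, for example along transcript length, so this excess is not a test. With total counts in place of TMM factors, 507 genes were higher and 223 lower (69.5% higher, against 48%). With the trend on exon length removed, an alternative added after seeing the data, 187 were higher and 83 lower (69.3% higher). With the stage score as a covariate, also added later, 798 genes were higher and 770 lower. The total of 492 became 260 without vehicle library 1, 302 without vehicle library 4, and 264, 299, 324, 291 and 297 without vitamin D libraries 1, 2, 3, 4 and 6.

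**Figure D2:**
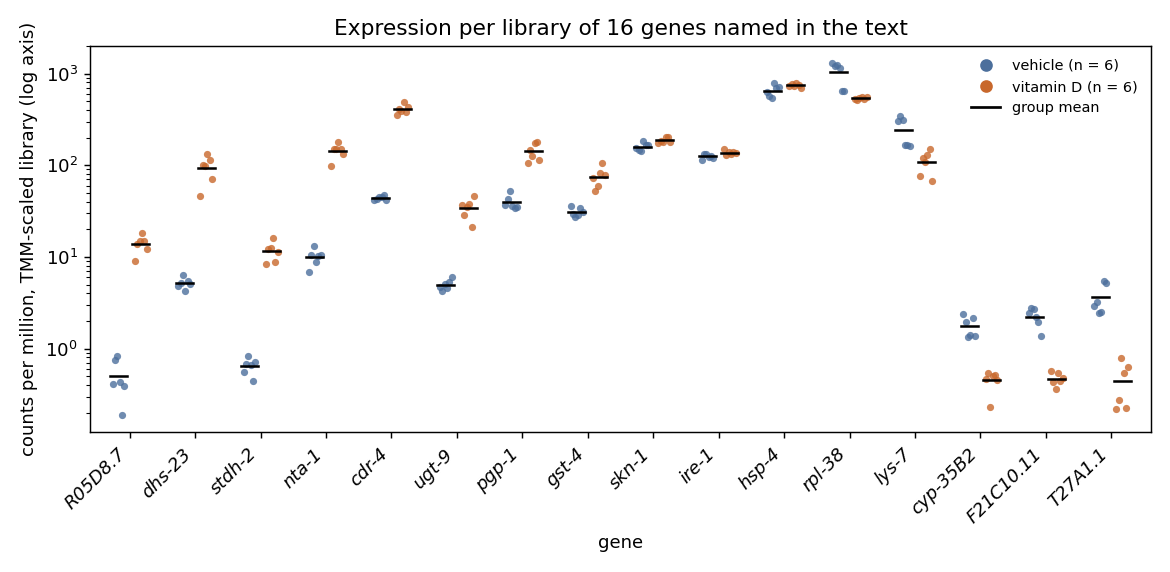
Expression of 16 named genes in each library, in CPM scaled by TMM factors on a log axis; each point is a library (6 vehicle, 6 vitamin D) and each line a group mean. R05D8.7 and stdh-2 lay near 1 CPM or below in all vehicle libraries and above 8 CPM in all vitamin D libraries, while skn-1, ire-1 and hsp-4 overlapped between groups.

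Among the 10 genes with the highest fold changes, dhs-23, a short-chain dehydrogenase on chromosome V (15381219 to 15382271), rose from 5.17 ± 0.68 to 93.9 ± 31.1 CPM. The steroid dehydrogenase family gene stdh-2 (V, 16224327 to 16225655) rose by 4.16 on the log2 scale (SE 0.21), from 0.644 ± 0.131 to 11.6 ± 2.91 CPM (edgeR adjusted p = 6.19e-07). The gene nta-1 (II, 3742465 to 3743814) rose by 3.83 (SE 0.18), 14.3-fold, and F25D1.5, another predicted short-chain dehydrogenase, by 3.47 (SE 0.28). R05D8.7 (V, 2761819 to 2763208) and R05D8.9 (V, 2766232 to 2767565) are neighbouring dehydrogenase genes, and R05D8.9 rose by 3.14 (SE 0.37). Reads shared between these similar genes could not be separated, so the level of each is uncertain. The other genes of this set were E02C12.10 (3.92, SE 0.54), the glucocerebrosidase gene gba-2 (3.60, SE 0.35) and cyp-34A10 (3.47, SE 0.52). The smallest p-values in the higher direction also included gst-39, which rose from 17.6 ± 2.35 to 63.4 ± 7.73 CPM.

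The strongest decrease was that of cyp-35B3 (V, 3945353 to 3947044), which fell from 1.89 ± 0.501 to 0.0339 ± 0.0471 CPM, with 0 counts in 2 of the 6 vitamin D libraries (edgeR adjusted p = 5.28e-05). Its neighbour and paralog cyp-35B2 (V, 3942160 to 3944523) fell by 1.96 on the log2 scale (SE 0.24), T27A1.1 by 3.01 (SE 0.38) and F21C10.11 by 2.24 (SE 0.20). Read sharing between both cyp-35B genes is possible, which leaves their separate levels uncertain. T22B7.7, F31D4.5 and tin-9.1, a subunit of the mitochondrial import machinery, were among the lower genes with the smallest p-values; they fell from 27.9 ± 4.37 to 13.1 ± 1.36 CPM, from 156 ± 18.1 to 96.4 ± 3.42 CPM and from 61.6 ± 5.17 to 41.7 ± 1.51 CPM. The remaining genes with large decreases were more variable: pud-3, clec-61, pud-2.2 (F15E11.1), F23A7.4, irld-23, Y47H9C.1 and nspc-18 fell by 2.74, 2.43, 1.76, 1.57, 1.53, 1.47 and 1.45, with edgeR adjusted p-values from 0.0246 to 0.0499. Each of these 7 lost its call in 10 to 20 of up to 31 alternatives.

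Of 19 tested SKN-1 phase II detoxification genes 8 rose, 0 fell and 11 did not pass, and 13 were higher and 1 lower when adjusted over the list alone. The glutathione S-transferases gst-4, gst-5, gst-6 and gst-7 had the smallest p-values of the list: gst-4, a widely used reporter of SKN-1 activity (IV, 10142225 to 10143099), rose 2.42-fold, by 1.27 on the log2 scale (SE 0.15, edgeR adjusted p = 0.000521). Levels of gst-7 went from 67.5 ± 5.55 to 197 ± 44.6 CPM, and of gst-6 from 63.5 ± 5.70 to 135 ± 16.7 CPM, while gst-5 rose by 1.56 (SE 0.21). The dehydrogenase gene dhs-8 had a larger change (2.75, edgeR adjusted p = 0.0106), and wdr-23, which encodes a protein that represses SKN-1, rose by 0.51. These 2 and the lower gene gstk-1 (-0.42) were picked out after their values were seen. The list's median log2 fold change was 1.03 (camera adjusted p = 9.05e-11, and adjusted p = 0.0981 with an estimated correlation). Its median per library was -0.73 to -0.16 in vehicle and 0.095 to 0.60 in vitamin D libraries (exact permutation p = 0.00216, 0.0324 adjusted over the lists).

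The gene skn-1 itself (IV, 5651039 to 5660384) had 160 ± 15.2 CPM on vehicle and 188 ± 11.7 CPM on vitamin D, a log2 fold change of 0.23 (SE 0.07, edgeR adjusted p = 0.0834). Its target gcs-1, of glutathione synthesis, had 0.30 (SE 0.08, edgeR adjusted p = 0.0707). Both passed when adjusted over the list alone and in some alternatives: adjusted p-values with the stage score as a covariate were 0.00146 for skn-1 and 0.00813 for gcs-1, and with the length trend removed 0.558 and 0.131.

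In the ER unfolded protein response and ERAD list, 1 of 22 tested genes rose, 0 fell and 21 did not pass; adjusted over the list alone, 3 were higher and 0 lower. The riser was marc-6, an ER ubiquitin ligase gene (0.19, SE 0.05, edgeR adjusted p = 0.0453, lost in 18 of 31 alternatives), and the other genes higher within the list were pek-1 (0.29) and atf-6 (0.30), which encode further sensors of ER stress. The level of ire-1 (II, 8112243 to 8124910) was 125 ± 7.51 CPM on vehicle and 137 ± 6.71 CPM on vitamin D (0.14, SE 0.05, edgeR adjusted p = 0.177). The ER chaperone gene hsp-4 had a log2 fold change of 0.20 (SE 0.08, edgeR adjusted p = 0.266). In some alternatives both passed: ire-1 in 3, for example with total counts (adjusted p = 0.0449), and hsp-4 in 3, for example with the stage score as a covariate (adjusted p = 0.00374). Of the 22 genes 21 had a positive sign, with a median of 0.14 (camera adjusted p = 0.000147, and adjusted p = 0.364 with an estimated correlation). Per library the list's median was -0.19 to -0.11 in vehicle libraries 1 and 4 to 6, but 0.06 and 0.10 in vehicle libraries 2 and 3. The vitamin D libraries had -0.04 to 0.13 (exact permutation p = 0.026, 0.111 adjusted over the lists). With the length trend removed marc-6 no longer passed, whereas with the stage score as a covariate 5 genes of the list were higher.

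Genes for cytochromes P450 and UDP-glucuronosyltransferases (UGTs), enzymes that modify foreign compounds, moved in both directions. Of 38 tested members 13 rose, 4 fell and 21 did not pass, and 19 were higher and 9 lower when adjusted over the list alone. Levels of ugt-9 went from 4.99 ± 0.668 to 34.1 ± 8.42 CPM, of ugt-16 from 38.9 ± 9.59 to 117 ± 9.97 CPM, and of cyp-33E2 from 18.4 ± 1.54 to 49.7 ± 7.59 CPM. The 4 that fell were cyp-35B3, cyp-35B2, cyp-35A2 (-1.13) and cyp-35A3 (-1.39), of which both cyp-35A genes are named after their values were seen. The list's median was 0.54 (camera adjusted p = 0.00268, and adjusted p = 0.364 with an estimated correlation). Its median per library was -0.32 to -0.09 in vehicle and -0.02 to 0.46 in vitamin D libraries (exact permutation p = 0.00216, 0.0324 adjusted over the lists).

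In the search over 110 symbol classes, whose members overlap with the lists, UGT genes had 18 higher and 1 lower of 63 tested (median 0.41, camera adjusted p = 8.69e-09), and theirs was the only class still past the threshold with an estimated correlation (adjusted p = 0.0216). Glutathione S-transferase genes had 10 higher and 0 lower of 37 (camera adjusted p = 3.89e-06, and adjusted p = 0.473 with an estimated correlation), and cytochrome P450 genes 12 higher and 4 lower of 61 (camera adjusted p = 0.00621, adjusted p = 0.691 with an estimated correlation, and 0.0661 with total counts for the cyp class). Nuclear hormone receptor genes had 7 higher and 1 lower of 193 (median 0.09, camera adjusted p = 0.0075), led by nhr-205, nhr-178, nhr-237 and nhr-106 with 1.82, 1.77, 1.72 and 0.72. Aspartyl protease genes had 2 higher of 12: asp-12 rose by 2.23 on the log2 scale (SE 0.17) and asp-14 from 279 ± 79.8 to 534 ± 66.8 CPM (camera adjusted p = 0.00262). With an estimated correlation the adjusted p was 0.799 for the receptors and 0.751 for the proteases, and with the length trend removed the receptors' camera adjusted p was 0.145; for the nhr class it was 0.385 with the stage score as a covariate and 0.112 without vehicle library 4. The dhs class of dehydrogenases did not pass, with 3 higher and 0 lower of 26 (median -0.01, camera adjusted p = 0.846).

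In the list of nuclear receptors related to the vertebrate vitamin D receptor and of steroid enzymes, 1 of 14 genes rose, 0 fell and 13 did not pass, and the counts were the same adjusted over the list alone. The riser was stdh-2. The receptors themselves did not pass: daf-12 had a log2 fold change of 0.31 (SE 0.16, edgeR adjusted p = 0.351), nhr-8 of -0.01 (SE 0.08) and nhr-48 of 0.04 (SE 0.09). The list's median was 0.17 (camera adjusted p = 0.0252, and adjusted p = 0.368 with an estimated correlation). Camera's adjusted p was 0.102 with the length trend removed, 0.0646 with the stage score as a covariate, 0.073 without vehicle library 6 and 0.0737 without vitamin D library 6.

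Intestinal markers rose in 4 of 22 tested genes, with 0 lower and 18 not past, and 8 were higher and 1 lower when adjusted over the list alone. The P-glycoprotein transporter gene pgp-1 (IV, 12591704 to 12599169) went from 39.7 ± 7.10 to 141 ± 31.2 CPM, and cdr-1 from 3.13 ± 0.486 to 5.78 ± 1.26 CPM, and the cysteine protease gene cpr-3 rose by 1.08 (SE 0.14). The fourth riser was erm-1 (0.20, SE 0.04), a membrane linker gene. The list's median was 0.14 (camera adjusted p = 0.00268, and adjusted p = 0.364 with an estimated correlation). It was 0.06 with the length trend removed and 0.03 with length and stage both corrected (camera adjusted p = 0.281, 5 higher and 1 lower), and 22.7% of these genes rose along the first component built without the stage lists.

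Innate immunity genes split: of 55 tested members 13 rose, 7 fell and 35 did not pass, and 16 were higher and 13 lower when adjusted over the list alone. F55G11.2, dod-24 and dod-17, which lie close together on chromosome IV, rose by 2.68, 1.74 and 1.49, and C32H11.4 rose by 3.02. The lysozyme gene lys-7 fell from 241 ± 83.8 to 109 ± 31.3 CPM. The list's median was -0.01 while its mean was 0.09 and camera's direction was up (adjusted p = 0.157); fry's test for change in either direction gave an adjusted p of 6.22e-09. With an estimated correlation the adjusted p was 0.764. Counts were 13 higher and 2 lower with the length trend removed (camera upward, adjusted p = 0.0118), 17 and 12 with the stage score as a covariate (0.73), and 16 and 10 with both (0.358). C-type lectin genes had 11 higher and 5 lower over all genes, and 23 higher and 9 lower when adjusted over the list alone. Examples were clec-210 (2.95), clec-76 (1.68) and clec-3 (1.32), and those that fell were clec-61, clec-86, clec-118, clec-8 and clec-48, the last 4 named after their values were seen. Their camera adjusted p was 0.0323, with an adjusted p = 0.364 with an estimated correlation and an adjusted p of 0.165 with total counts in place of TMM factors. The call was also lost with the stage score as a covariate (0.144) and without vehicle library 5 (0.0845), vehicle library 6 (0.073) or vitamin D library 4 (0.0597).

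**Figure D3:**
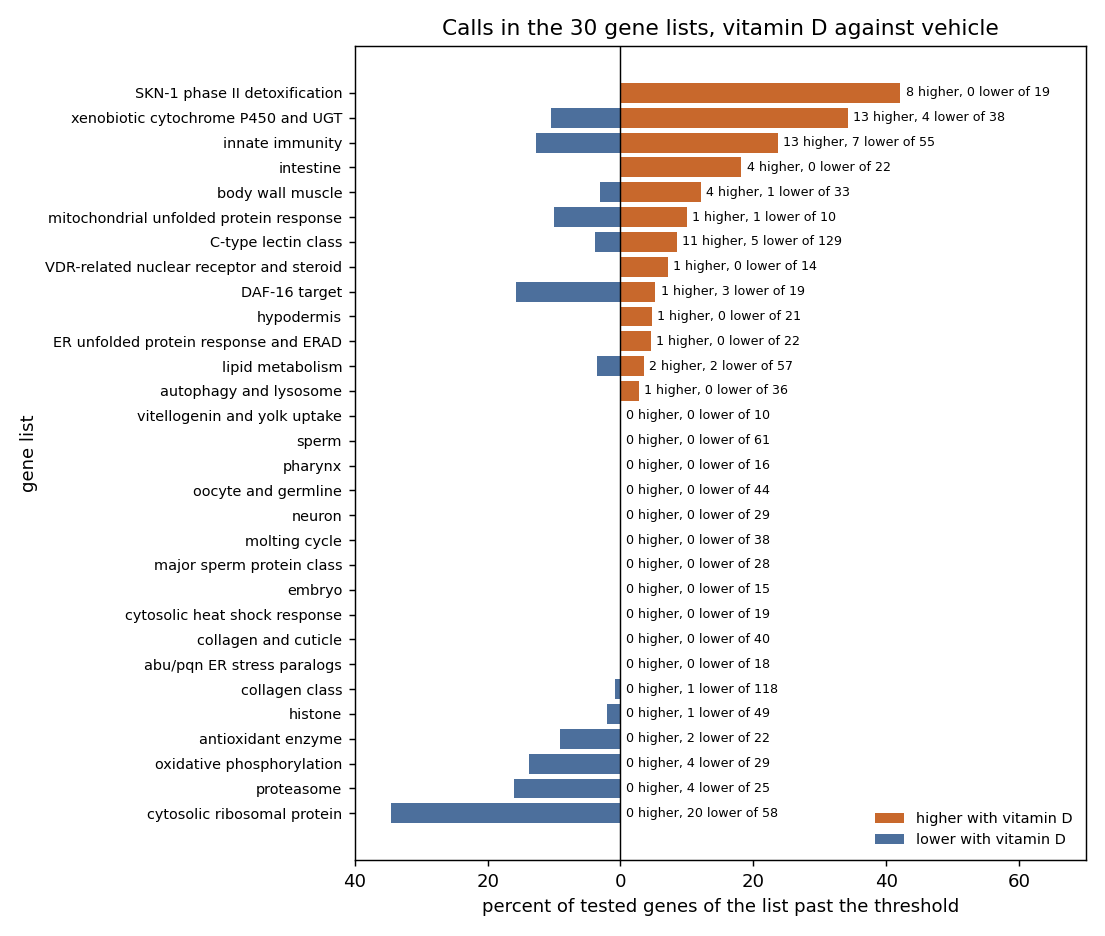
Share of the tested genes of each of the 30 lists that passed the threshold, in percent, to the right for genes higher with vitamin D and to the left for genes lower; counts are printed beside the bars. SKN-1 phase II detoxification has the longest bar to the right (8 of 19) and cytosolic ribosomal proteins the longest to the left (20 of 58).

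Of 58 tested cytosolic ribosomal protein genes 20 fell, 0 rose and 38 did not pass; 42 were lower and 0 higher when adjusted over the list alone. Examples with smaller changes than rpl-29 and rpl-38 were rps-16 (2294 ± 253 to 1709 ± 56.3 CPM), rps-19 (-0.40, SE 0.08) and rpl-10 (4225 ± 337 to 3411 ± 128 CPM). The list's median was -0.25 (camera adjusted p = 1.97e-26, and adjusted p = 0.364 with an estimated correlation). Per library, the median of these genes was 0.14 to 0.27 in vehicle libraries 1 to 4, but -0.10 in vehicle libraries 5 and 6, within the -0.16 to -0.09 of the vitamin D libraries (exact permutation p = 0.00866, 0.052 adjusted over the lists). In the search over classes, rps genes had 10 lower of 22 and rpl genes 8 lower of 35 (camera adjusted p = 8.9e-16 and 2.47e-14; adjusted p = 0.695 and 0.751 with an estimated correlation).

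Beyond the ribosomal protein genes, short transcripts were lower with vitamin D among well-expressed protein-coding genes, those with a mean log2 CPM over 3. The median log2 fold change was -0.83 for the 49 such genes of up to 300 nt of exon and -0.55 for the 125 of 300 to 400 nt. It was -0.04 for the 2032 of 1000 to 1500 nt and 0.17 for the 295 over 5000 nt. The median deviation of well-expressed genes under 400 nt was 0.30 ± 0.22 in vehicle and -0.25 ± 0.09 in vitamin D libraries (SD, n = 6 and 6; exact permutation p = 0.00216, the smallest that 6 against 6 can give). Of the 256 genes that fell, 182 were under 800 nt, a length under which 20.6% of tested genes lay. With the trend removed, 3 of the 20 ribosomal protein genes still passed, and their median moved from -0.39 (quartiles -0.57 and -0.31) to -0.17 (quartiles -0.38 and -0.10). The list of 58 still passed camera (median -0.04, adjusted p = 0.000248), as did rps (0.00418) and rpl (0.0425), and with length and stage both corrected 13 of its genes were lower.

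Other library properties moved with the treatment too. Ribosomal RNA took 1.165% ± 0.368% of the counts in vehicle and 0.634% ± 0.201% in vitamin D libraries (SD, n = 6 and 6; exact permutation p = 0.00649, 0.0216 adjusted over 10 properties). The 10 most abundant genes took 5.29% and 4.71% (exact permutation p = 0.00433), and pseudogenes 0.918% and 0.823% (exact permutation p = 0.0173). Identifiers without a match took 0.518% to 0.577% in vehicle and 0.594% to 0.653% in vitamin D libraries.

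**Figure D4:**
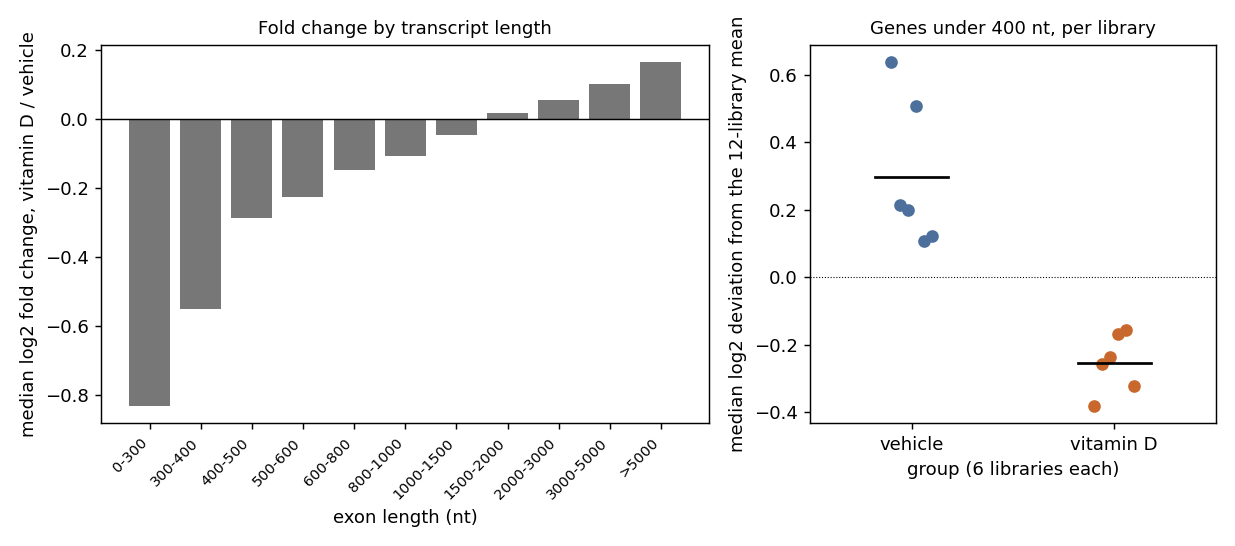
Left, median log2 fold change (vitamin D over vehicle) of protein-coding genes with a mean log2 CPM over 3, in bins of exon length in nt. Right, median log2 deviation of such genes under 400 nt in each library (points, 6 vehicle and 6 vitamin D) with group means (lines). The medians rise from -0.83 in the shortest bin to 0.17 in the longest, and the 6 vitamin D libraries lie below all 6 vehicle libraries.

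Of the proteasome, the protein-degrading complex, 4 of 25 tested subunit genes fell, 0 rose and 21 did not pass, and 11 were lower and 0 higher when adjusted over the list alone. The core subunits were pas-3 (365 ± 17.6 to 307 ± 6.14 CPM), pbs-4 (245 ± 20.7 to 201 ± 2.65 CPM), pbs-3 (-0.21, SE 0.05) and pbs-7 (-0.15, SE 0.04), the last 2 lost in 19 of 31 alternatives. The median was -0.12 (camera adjusted p = 6.98e-10, and adjusted p = 0.364 with an estimated correlation). The 4 genes had 801 to 893 nt of exon, and with the length trend removed 0 genes passed while camera still did (adjusted p = 0.000993). With length and stage both corrected 4 genes were lower.

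Oxidative phosphorylation genes had 4 lower, 0 higher and 25 not past of 29, and 12 lower when adjusted over the list alone. Those that fell were ucr-11 (134 ± 36.7 to 70.4 ± 5.17 CPM), hpo-18 (210 ± 64.3 to 116 ± 4.78 CPM), asg-1 (-0.36) and nuo-6 (-0.33), with 281 to 650 nt of exon. The median was -0.13 (camera adjusted p = 4.62e-08, and adjusted p = 0.473 with an estimated correlation). Per library it was 0.07, 0.29 and 0.28 in vehicle libraries 1 to 3, but -0.12 to -0.01 in vehicle libraries 4 to 6. The vitamin D libraries had -0.149 to 0.002 (exact permutation p = 0.126, 0.315 adjusted over the lists). With the length trend removed 1 gene passed and camera still did (adjusted p = 0.004). In turn 20 genes were lower with the stage score as a covariate (camera adjusted p = 1.61e-17), and with length and stage both corrected 10. The transthyretin-like class had 10 lower and 0 higher of 42 (camera adjusted p = 8.73e-06, and adjusted p = 0.548 with an estimated correlation), led by ttr-35 (-0.60). With the trend removed the class had 1 lower gene, its median moved from -0.26 to -0.05 and its camera call was lost (adjusted p = 0.283). The classes nspc, cyn, mrps, mdt and mrpl had 3, 3, 3, 1 and 0 lower genes with camera adjusted p-values of 1.88e-07, 0.00712, 0.00796, 0.0277 and 0.00796; adjusted p-values with an estimated correlation ran from 0.448 to 0.799. With the trend removed 0 genes of any of the 5 classes were lower, and of the 5 only nspc still passed camera (median -0.45, adjusted p = 6.07e-05).

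Besides the nuclear receptors, the unc, egl and let classes passed upward only before the length trend was removed. The unc genes had 6 higher and 0 lower of 75 (median 0.13, camera adjusted p = 4.76e-06, and adjusted p = 0.799 with an estimated correlation), among them unc-132, unc-54, unc-89 and unc-115 with 0.25, 0.24, 0.20 and 0.20. The egl and let classes had 0 and 1 higher genes (let-363, 0.19) and camera adjusted p-values of 0.00531 and 0.00572 (adjusted p = 0.799 and 0.695 with an estimated correlation). With the length trend removed, their camera adjusted p-values were 0.391, 0.324 and 0.825 and 0 of their genes passed. Proton pump genes of the vha class had 2 higher of 17, vha-7 and vha-19 (0.34 and 0.45; camera adjusted p = 0.0484, and adjusted p = 0.809 with an estimated correlation), and 2 with the trend removed. The call of the vha class was lost with the stage score as a covariate (0.299) and without vehicle library 4, 5 or 6 (0.123, 0.133 and 0.0908) or vitamin D library 1 or 6 (0.0883 and 0.112).

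Body wall muscle genes had 4 higher and 1 lower of 33 with 28 not past, and 6 higher and 4 lower when adjusted over the list alone; camera found no direction (adjusted p = 0.99). The myosin and giant sarcomere genes unc-54 (2473 ± 203 to 2919 ± 63.1 CPM), unc-89 and ketn-1 rose by 0.24, 0.20 and 0.26, as did unc-68 by 0.22, named after its value was seen. The shorter cpn-3, with 612 nt of exon against 6204 nt for unc-54, fell by 0.36. With the length trend removed 0 genes of the list passed, while camera passed downward (adjusted p = 0.0368, and 0.00724 with length and stage both corrected). The calls of unc-54, unc-89 and ketn-1 were lost in 15, 14 and 13 of 31 alternatives.

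DAF-16 targets, readouts of insulin signalling, had 1 higher and 3 lower of 19, 15 not past, and 1 higher and 4 lower when adjusted over the list alone (median -0.18, camera adjusted p = 0.0748). Camera passed downward with the length trend removed (adjusted p = 0.0234), with the stage score as a covariate (0.0204, 7 genes lower) and with both (0.00724), but not with an estimated correlation (adjusted p = 0.364), and the direction turned on 8 libraries (adjusted p = 0.983). Those that fell were lys-7, ttr-44 (-0.86) and nnt-1 (-0.65), and acs-17 rose by 0.33. With the length trend removed 0 genes of the list were higher and 1 was lower. The superoxide dismutase gene sod-3 had a log2 fold change of -0.06 (SE 0.23, edgeR adjusted p = 0.92) and daf-16 of 0.10 (SE 0.06, edgeR adjusted p = 0.461). Antioxidant enzymes had 0 higher and 2 lower of 22, glrx-22 (-0.33) and glrx-10 (-0.25), 20 not past, and 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.554). Both glutaredoxin genes lost their calls with the length trend removed (-0.11 and -0.04), and 2 other genes were higher and 0 lower.

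In the cytosolic heat shock response, 0 of 19 genes passed in edgeR over all genes or when adjusted over the list alone (median -0.02, camera adjusted p = 0.569); 0 had an unadjusted p under 0.05 and 0 passed in DESeq2. With the stage score as a covariate 1 was lower, and in the fit on 8 libraries, where stage and treatment coincide, 2 were higher and 2 lower. Its regulator hsf-1 had 0.06 (SE 0.07, edgeR adjusted p = 0.713) and the small heat shock gene hsp-16.2 had 0.65 (SE 0.57, edgeR adjusted p = 0.616) at 0.339 ± 0.30 and 0.532 ± 0.108 CPM. Its relative hsp-16.41, with 0 to 12 counts per library, was below the filter, so a change there was not detectable at this depth. In the mitochondrial unfolded protein response, 1 of 10 genes rose (lonp-1, 0.22), 1 fell (ubl-5, -0.87, 327 nt of exon) and 8 did not pass, with 1 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.475). The call of lonp-1 was lost in 20 of 31 alternatives, leaving out any 1 library among them (edgeR adjusted p from 0.0537 to 0.132). The chaperone gene hsp-6 had 614 ± 29.2 and 648 ± 89.1 CPM (edgeR adjusted p = 0.693).

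Lipid metabolism genes had 2 higher and 2 lower of 57, 53 not past, and 2 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.203). With the stage score as a covariate 3 were higher and 16 lower and camera passed downward (adjusted p = 0.000612), and in the fit on 8 libraries 19 were higher and 9 lower. The lipid-binding protein gene lbp-8 rose from 1.87 ± 1.09 to 15.4 ± 1.96 CPM and ech-9, an enoyl-CoA hydratase gene, rose by 2.14, while lbp-5 and lbp-3 fell by 0.89 and 0.31. Autophagy and lysosome genes had 1 higher (lmp-2, 0.40) and 0 lower of 36, and 2 higher when adjusted over the list alone (camera adjusted p = 0.0811, but 0.0139 without vehicle library 2, 0.0188 without vehicle library 3 and 0.015 with total counts). In the hypodermis list vha-7 rose and the 20 other genes did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.317).

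Genes of the germline, of yolk and of the cuticle varied more between pools than between treatments. In edgeR 0 genes passed over all genes or when adjusted over the list alone among 61 sperm, 28 major sperm protein, 44 oocyte and germline, 18 abu/pqn, 40 collagen and cuticle, 38 molting, 15 embryo, 29 neuron and 16 pharynx genes. Unadjusted p-values under 0.05 were held by 1, 0, 1, 0, 2, 2, 2, 7 and 1 of them, and DESeq2 called 1 molting gene lower, 2 neuron genes higher and 1 pharynx gene higher. With length and stage both corrected, 17 sperm and 15 major sperm protein genes were higher. The stage score is built partly from the sperm list, which holds major sperm protein genes, so this is no independent test of them. Without vehicle libraries 2 and 3 and vitamin D libraries 1 and 5, where stage and treatment coincide, 52 sperm, 27 major sperm protein and 35 oocyte and germline genes were lower and 12 neuron genes higher. Among 10 vitellogenin and yolk genes, 0 passed over all genes and 1 was higher adjusted over the list alone (dsc-4, 0.35). The yolk gene vit-2 had 592 ± 423 CPM on vehicle and 508 ± 1048 CPM on vitamin D (-0.22, SE 1.14, edgeR adjusted p = 0.942). Camera adjusted p-values were 0.0916 for major sperm proteins, 0.0753 for oocyte and germline, 0.318 for abu/pqn, 0.441 for collagen and cuticle, 0.251 for molting, 0.219 for embryo, 0.075 for pharynx and 0.126 for vitellogenins. Several of these depended on single libraries or corrections. Oocyte and germline genes passed downward with the length trend removed (0.000993) and without vehicle library 2 (0.0033), vehicle library 3 (0.00222) or vitamin D library 5 (1.59e-05). Vitellogenins did so with the length trend removed (0.0118) and without vitamin D library 5 (0.00381), and major sperm proteins without the same 3 libraries (0.00102, 0.000131 and 0.0278). Pharynx genes passed upward without vehicle library 1, 2 or 3 (0.0413, 0.0361 and 0.011), molting genes without vehicle library 2 (0.0498), and abu/pqn genes passed downward without vehicle library 3 (0.0324).

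The sperm list, with a median of -0.70 and 0 of its 61 genes past, had a camera adjusted p of 0.0323 and an adjusted p = 0.764 with an estimated correlation. That call was lost with the length trend removed (0.0512) and without vehicle library 1, 4, 5 or 6 (0.188, 0.538, 0.376 and 0.316) or vitamin D library 1, 2, 3 or 6 (0.0815, 0.0692, 0.0635 and 0.0737). Its median per library was 0.18 ± 1.44 in vehicle and -0.15 ± 0.41 in vitamin D libraries (exact permutation p = 0.552). Camera's direction turned with the stage score as a covariate (adjusted p = 0.0646). That score is itself built partly from the sperm list. Neuron genes had a median of 0.17 (camera adjusted p = 0.0035, adjusted p = 0.731 with an estimated correlation, and 0.144 with the stage score as a covariate), and 3.4% of them rose along the first component built without the stage lists. The collagen class had 1 lower gene of 118, col-2 (-1.33), also when adjusted over the list alone, and a median of -0.41 (camera adjusted p = 0.000393, and adjusted p = 0.731 with an estimated correlation). Along that component 85.6% of the collagen genes rose, and with the stage score as a covariate their median was 0.01 (camera adjusted p = 0.236). Histone genes had 1 lower of 49, his-51 (K06C4.3, -0.98), also when adjusted over the list alone, and a median of -0.27 (camera adjusted p = 7.04e-06, and adjusted p = 0.364 with an estimated correlation). The median was -0.07 and 0 genes passed with the length trend removed (camera adjusted p = 0.0198; his-51, edgeR adjusted p = 0.0573). Histone genes are near-identical copies, so their separate counts are uncertain.

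Of the 30 lists, 7 passed camera's test upward and 6 downward with the preset correlation, and 0 passed with an estimated correlation. Fry's directional adjusted p-values for those upward were 0.000278 (SKN-1), 0.00618 (P450 and UGT), 0.00998 (intestine) and 0.0123 (VDR-related). They were 0.0123 for C-type lectins, 0.0311 for the ER list and 0.235 for neurons. For those downward they were 0.014 (proteasome), 0.0171 (ribosomal), 0.0964 (oxidative phosphorylation), 0.0964 (histone), 0.463 (collagen class) and 0.776 (sperm). Of the 110 classes, 9 passed upward and 10 downward, and 1 with an estimated correlation. The 13 lists kept their direction with DESeq2's size factors and with total counts. At least as many lists passed in 34 of 100 splits of the 12 libraries into groups of 6, the real split included, and at least as many classes in 35, so the camera counts alone do not set the treatment apart from other groupings.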

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

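The test of equal decreases among ribosomal protein genes, the stage and the vitamin D explanations of the first component, and both tests on chromosome III were chosen only after the result was seen. A value was singled out when a library's gap to its nearest neighbour, divided by the range of its group of 6, exceeded Dixon's 95% critical value. This happened in 18 of 324 groups, where chance alone gives about 1 in 20 groups (5%). For 8 of the 18 the library was vitamin D library 5.

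Among genes, the gap was 0.676 of the range for cyp-35B3 (vitamin D library 4 highest), 0.766 for cyp-35B2 (vitamin D library 3 lowest), 0.673 for col-2 (vehicle library 3 lowest) and 0.687 for hpo-18 (vitamin D library 5 lowest). It was 0.755 for cyn-7 and 0.695 for vit-2 (both vitamin D library 5 highest), 0.711 for pbs-7 (vehicle library 5 lowest), 0.759 for dod-24 (vehicle library 1 lowest), 0.674 for clec-210 (vehicle library 3 highest) and 0.668 for lbp-8 (vitamin D library 6 highest). For vit-2 the library's log2 CPM was 11.37 against 6.87 in the next.

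Among list medians, vitamin D library 5 was highest for the vitellogenin list (0.689), the sperm list (0.642), the oocyte and germline list (0.983) and the major sperm proteins (0.665), and lowest for the ER unfolded protein response (0.646). Vitamin D library 1 was lowest for the abu/pqn list (0.751) and vehicle library 3 highest for the heat shock list (0.628). Vitamin D library 4 had the lowest total count of its group (0.643), 31383203 against 36102172 in the next.

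The lower ribosomal protein genes and other short transcripts were weighed against a length trend between libraries, differences in stage and a decrease of equal size. With the length trend removed, 3 of the 20 ribosomal protein genes stayed past the threshold, and their median log2 fold change moved from -0.39 (quartiles -0.57 and -0.31) to -0.17 (quartiles -0.38 and -0.10), which is consistent with a length trend between libraries as a large part of the pattern; the list as a whole still passed camera (adjusted p = 0.000248). With the stage score as a covariate all 20 stayed, so differences along that score do not account for these calls. Treatment groups did not clearly differ on the score (exact permutation p = 0.437), so the fit had little to remove. Differences in stage that the score does not capture stay open. The shorter ribosomal protein genes differed from the longer ones by -0.137 in median log2 fold change (-0.32 against -0.18), but other genes of these lengths had -0.32 and -0.10, so the trend fixes this outcome and a decrease of equal size on top of it stays open. Whether the trend arose in the library preparation or in the worms cannot be read from these data, because it coincides with the treatment.

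The spread of libraries of the same treatment along the first principal component was weighed against stage, transcript length and the treatment. Along a component built without the stage lists, 96.7% of the sperm genes rose, as pools at different developmental stages would give. The component's direction was set by the stage score, which is built partly from sperm genes, and unlisted germline genes may remain in it. The value therefore shows that sperm genes varied together along the component, and stage as the reason stays open. With the length trend removed the first component still held 63.8% of the variance, so the trend does not account for it. The vehicle libraries alone covered 100% of its range, so the treatment is not needed for it.

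All chromosome III genes stood at 0, and 0 of its 2800 entries had a count in any library, which is consistent with that chromosome having been left out when reads were aligned or counted. Low expression was excluded: proteasome genes on the other chromosomes had a median of 248.5 CPM, while the 7 proteasome genes on chromosome III stood at 0. No other biological explanation was tested. The gene xbp-1 lies in this gap.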

How the results depend on the processing

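The length correction, the stage score as a covariate, both together and the fit on 8 libraries were chosen only after the result was seen. With the length correction camera also used unweighted log2 counts in place of voom values, so its p-values reflect both changes. The count of 492 genes was 1136 (543 higher, 593 lower) with DESeq2, 5781 (2908, 2873) with voom quality weights, 1418 (675, 743) with a surrogate variable, 72 (66, 6) against a 1.5-fold change and 153 (1.0e+02 to 2 digits, 52) at 0.01. It was 270 (187, 83) with the length correction, 1568 (798, 770) with the stage score, 1024 (641, 383) with both and 4998 (2224, 2774) with 8 libraries, in which stage and treatment coincide (scores of 0.84 to 1.41 in vehicle, -0.41 to -0.07 in vitamin D libraries), and total counts gave 507 higher. Leaving out 1 library gave 260 to 625 genes, 146 to 308 higher and 109 to 317 lower. The lists past the threshold became 22 with 8 libraries and 0 with an estimated correlation, and the classes 10 with the length correction, 11 with length and stage and 1 with an estimated correlation. Apart from the replicate block below, other settings kept these counts within 1.5 times; the cause was not tested, except that fewer genes pass a stricter threshold.

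With the replicate number as a block, 136 genes passed (1.0e+02 higher to 2 digits, or 76.5%, and 32 lower), 46 of the 107 named genes past the threshold among them; those not past it included cyp-34A10, rpl-38, pas-3 and lys-7. Correlations of same-numbered libraries, as deviations from group means, were -0.42, -0.04, -0.04, 0.30, 0.44 and -0.31, which shows no common pairing. The first component holds 56.2% of the variance over all tested genes and bears on these values. They therefore cannot exclude that same-numbered pools shared a day or batch.

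Directions turned for lists as follows, with camera adjusted p-values. Because the stage score is built partly from the sperm and abu/pqn lists, turns of abu/pqn, sperm and major sperm protein genes with it are circular. With the stage score: abu/pqn 0.453, collagen and cuticle 0.483, sperm 0.0646, oocyte and germline 0.453, major sperm proteins 0.0191. With length and stage: abu/pqn 0.550, antioxidant 0.333, collagen and cuticle 0.923, autophagy 0.899, sperm 2.2e-08, hypodermis 0.550, major sperm proteins 1.04e-10, mrpl 0.964. With length: antioxidant 0.0673, mrpl 0.337, mrps 0.892. With 8 libraries: DAF-16 targets 0.983, antioxidant 0.919, lipid 0.0311, body wall muscle 0.0139. Body wall muscle also turned with total counts (0.361), the replicate block (0.890) and fry (0.843). Leaving out 1 library gave 0.0324 to 0.821 for abu/pqn, 0.292 to 0.978 for heat shock and 0.219 to 0.944 for body wall muscle.

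Log2 fold changes that turned were those of vit-2 (0.082 surrogate variable, 0.165 stage, 0.041 length and stage), sod-3 (0.036 surrogate variable, 0.075 length, 0.027 stage, 0.145 both), nhr-8 (0.056 total counts, 0.011 weights, 0.007 with 8 libraries) and nhr-48 (-0.012 surrogate variable, -0.055 length, -0.008 stage, -0.093 both). Others were hsf-1 (-0.021 weights, -0.005 length, -0.017 with 8 libraries), hsp-6 (-0.017 weights, -0.032 with 8 libraries), daf-16 (-0.018 length, -0.026 both) and unc-89 (-0.020 length). Leaving out 1 library gave -2.884 to 0.031 for vit-2, -0.242 to 0.039 for sod-3, -0.047 to 0.023 for nhr-8 and 0 to 0.094 for nhr-48. Of these genes only unc-89 had passed the threshold, and the cause was not tested. Of the 107 named genes past the threshold, 98 stayed past it with total counts, 59 with the length correction and 107 with the stage score.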

Other observations

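The neighbour tests below were fixed before their results were seen, while the use of the stage score and the runs of genes named here were chosen only after the result was seen. Genes that rose with vitamin D often lay next to each other. On chromosome II, cyp-13A3, cyp-13A4, cyp-13A5, cyp-13A6 and cyp-13A7 (9788797 to 9805513) rose by 1.06 to 3.27 on the log2 scale, 5 of the 6 tested genes of that span. On chromosome V, ugt-8, ugt-9, ugt-10, ugt-11 and ugt-14 (4892588 to 4908304) rose by 1.42 to 2.77 (5 of 6), and R05D8.7, dhs-14 and R05D8.9 (2761819 to 2767565) by 0.86 to 4.78 (3 of 3). On chromosome IV, K08D8.3, K08D8.4, C32H11.4 and dod-24 (12903785 to 12941354) rose by 0.33 to 3.02, 4 of the 13 tested genes of that span. These runs were chosen after their values were seen, and paralogs in them may share reads, so that fewer than the 95 genes counted next may have changed on their own.

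Of 233 higher genes with a position, 95 had another higher gene within 20000 bp, against a median of 32 for random sets of tested genes (one-sided permutation p = 1e-04, the smallest possible). Counting only neighbours of another class or of none, 64 did, against 31, but only 10 of the 46 such pairs had a class name for both genes, so unnamed paralogs are counted in and gene families stay open as the source. Lower genes did so in 60 of 256 cases, against 33 (one-sided permutation p = 3e-04). Chromosome I held 15 of the 236 higher and 71 of the 256 lower genes among its 2446 tested genes.

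The 12 libraries were also split into other groups of 6, with 100 splits in all. At least 492 genes passed in 5 splits, the real one included, and the highest count among the others was 3855, so the count alone does not exclude chance. The absolute correlation with the stage score was at least 0.70 in the other 4 and 0.24 in the real split, and 0 genes passed in each of the 85 others with a correlation under 0.5. At least 13 lists passed in 34 splits (at most 19) and at least 19 classes in 35 (at most 34), which other groupings of these libraries can therefore give. With the stage score as a covariate, 1568 genes passed in the real split. It alone (1 of 100) reached that count, with at most 3 in any other. The libraries are not freely exchangeable, though: chi-square per degree of freedom went down to 7.8 within a group but only to 72.2 between groups. The real split keeps close libraries together, and library properties that moved with the treatment could set it apart too. The splits therefore cannot tell the treatment from such properties.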
